A study of Homo sapiens with 9 samples.

How the data were processed

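Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in 786-O and A498, established human cell lines derived from clear cell renal cell carcinoma. Cells edited with a guide RNA and donor plasmid to carry an eGFP-containing tag at the ZNF395 gene, which encodes a zinc finger transcription factor, were precipitated with an antibody against GFP, as were unedited parental cells. Parental 786-O cells were also precipitated with an antibody against the transcription factor MYC. Per the labels' protocols, chromatin was fixed with 1% formaldehyde for 10 min and sonicated to about 500 bp, 20 µg of antibody was used, and libraries were sequenced to an average of 30 to 50 M reads. The series holds 9 samples, of which 5 have a peak list; the 4 input samples have none and entered only as the controls the authors called peaks against.

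Per the submitters' processing notes, BWA and MACS2 were used with the hg19 build; their roles, versions and settings are not given in the sources used here. The deposited lists are 5-column peak tables without headers, and their peak names state, in the deposited files, that alignments were merged, sorted and processed by mapping quality and that each library was called against 1 control library. The MYC list and the parental 786-O GFP list name the same control library, and each of the other lists names its own. The deposited score of each peak was read as a −log10 value of a p or q: each of the 5 lists begins just above 2, as a threshold of 0.01 would give, but whether it is a p or a q is not given in the sources used here. Scores are the authors' and were used to rank a list, to keep its upper 50%, to divide it into 10 equal parts, to compare medians between parts of the same list and, as ranks, in correlations between lists; sizes of scores were not compared between lists, because a score depends on the depth and the control of its own library. No list gives read counts, so the depth behind single peaks is unknown, and how many reads each library really had cannot be weighed against its number of peaks.

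Groups were taken from the sample titles, with 1 library per group. Titles conflict with other label fields in places: the samples titled A498 carry 786-O in the cell line field, and the MYC sample names P300, a coactivator found at active regulatory regions, in the target field, while its title and antibody field name MYC. In the text, A498 and MYC mean the libraries so titled. With 1 library per group no test across replicates was possible, no p-value is given, and no difference has a replicate check.

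Peaks were compared by overlap of at least 1 bp. A tagged-only peak is a peak of the tagged cells with no overlapping peak in the parental list of the same line. Lack of a parental peak does not show that such a peak is free of antibody background. Background below the calling threshold of the 1 parental library would not be removed. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only and treat peaks as independent. Overlap shares of whole lists and tagged-only lists were set beside 1000 random placements of the same peaks. Widths were kept, and peaks stayed within the span that the 5 lists cover on each chromosome. Shares in parts by score, in bins, chromosomes and blocks, and under the alternatives had no such placements. In a placement alternative added after the data were seen, each peak was moved at random within 50 kb of its place. Differences in median score between parts of a list carry 95% intervals from 1000 bootstrap draws of peaks. Correlations of scores are across peaks, which are not independent replicates. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap rules were tested on simulated data, where 0 of 5000 peaks per run were called wrongly, and on 20034 randomly moved peaks, where 0 differed from bedtools 2.31.1.

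The comparisons of tagged with parental peaks, of tagged-only peaks between lines and of these with MYC were fixed before the data were examined. So were the alternatives, except placement within 50 kb and removal of the 1 Mb bins dense in parental peaks. The other comparisons and the numbers of peaks named are not claimed to have been fixed in advance. Since no hg19 annotation was used here, peaks are named by position: the 10 of highest score among the tagged-only peaks of each line, the 10 of best rank sum in both lines, and 5 for each part of the comparisons with MYC, with the parental lists and of line-specific peaks. Ties were broken by width and then by position. Genes at the peaks, shares of peaks at promoters, the gene lists and the sequence motifs that had been planned all need an hg19 annotation or sequence and were not analysed here. Alternatives covered a 50% reciprocal overlap, midpoints within 200 bp, the upper 50% of each list by score, lists limited to equal length by score, removal of the widest 1% of peaks, removal of unplaced contigs and the mitochondrial genome, and other ways of subtracting parental peaks (none, parental peaks extended by 1 kb, or the peaks of either parental list removed from both lines). Coordinates are hg19 and counted from 1.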

Results

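To locate ZNF395 on chromatin in renal carcinoma cells, GFP ChIP-seq was compared between cells carrying eGFP at ZNF395 and parental cells without it, in 786-O and in A498, and with MYC ChIP-seq in parental 786-O. The authors' lists held 20034 peaks for tagged 786-O, 3361 for parental 786-O, 7718 for tagged A498, 1563 for parental A498 and 20199 for MYC. Tagged 786-O peaks had a median width of 393 bp and covered 10567 kb, close to the 425 bp and 10805 kb of the MYC list. Tagged A498 peaks were narrower, with a median of 245 bp, and covered 2380 kb. The parental lists covered 850.4 kb in 786-O and 382.9 kb in A498. Each group was 1 library, so no difference has a replicate check and the intervals given cover counting error only.

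**Figure D1:**
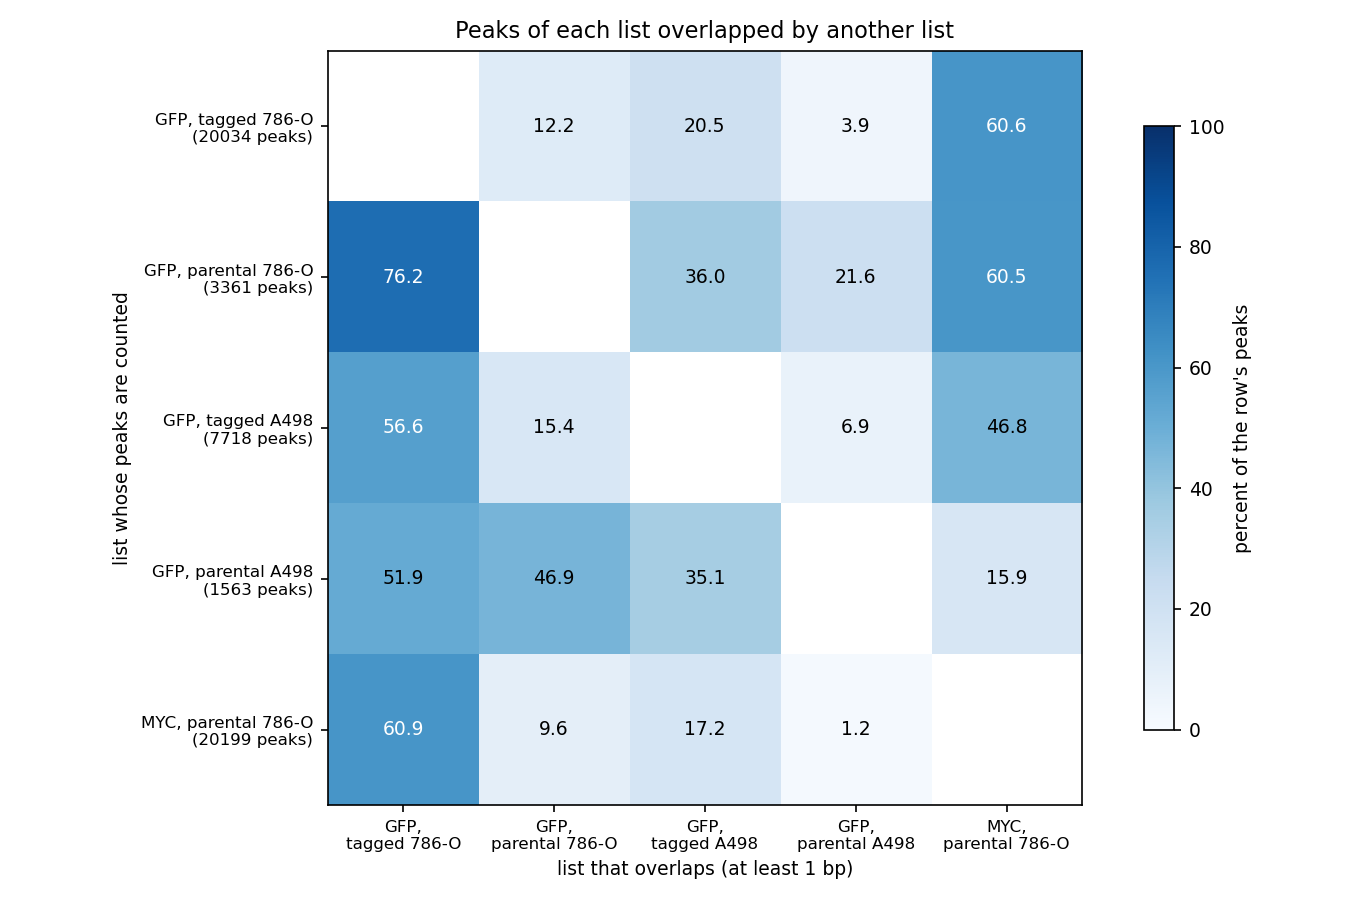
Percent of the peaks of each list (rows, with the number of peaks) that overlapped a peak of each other list (columns) by at least 1 bp; darker blue is a higher percent. The highest value is the 76.2% of parental 786-O peaks found again in tagged 786-O, while 12.2% of tagged 786-O peaks lay at parental peaks.

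In 786-O, GFP peaks were 5.96 times as many in tagged as in parental cells, and the 4 highest-scoring tagged peaks had no parental peak. The highest-scoring tagged peak lay on chromosome 11 at 8008444 to 8009350, with a score of 313, and the next on chromosome 5 at 25544631 to 25545427, with a score of 299.6. Among tagged-only peaks they were followed by sites on chromosome 19 at 49621787 to 49623557 (score 263), chromosome 2 at 39455162 to 39455812 (score 260.4) and chromosome 12 at 4429864 to 4430999 (score 249.8). Sites on chromosome 17 at 66031473, chromosome 16 at 89159947 and 68297870, chromosome 8 at 41908489 and chromosome 11 at 34378905 completed the 10 highest tagged-only peaks, whose scores ranged from 240.5 to 313. None of these 10 had a parental peak in either line. All 10 had a tagged A498 peak, and 7 had a MYC peak.

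Of the 20034 tagged 786-O peaks, 2438 (12.2%, 95% interval 11.7 to 12.6) overlapped a parental 786-O peak, which left 17596 tagged-only peaks. Random placement gave a mean of 0.118%. In the other direction, 2561 of the 3361 parental peaks (76.2%, 74.7 to 77.6) were also called in tagged cells. Tagged peaks at parental sites had a higher median score (27.0) than tagged-only peaks (11.8), a difference of 15.2 (14.2 to 16.4). The share of tagged peaks at parental sites was 3.80% when a 50% reciprocal overlap was required and 26.8% when both lists were limited to their 3361 highest peaks.

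In A498, tagged cells gave 4.94 times as many GFP peaks as parental cells, and the highest tagged-only site was the one on chromosome 11, at 8008542 to 8009322, with a score of 223. It was followed by chromosome 16 at 4233597 to 4234597 (score 222), chromosome 1 at 46598193 to 46599145 (score 187), chromosome 4 at 106629544 to 106630153 (score 179.6) and chromosome 1 at 184020634 to 184021275 (score 174.9). The remaining 5 of the 10 highest tagged-only A498 peaks were on chromosome 19 at 49622109, chromosome 16 at 68298004, chromosome 12 at 4429990, chromosome 1 at 222817261 and chromosome 11 at 34379018. All 10 had a peak in tagged 786-O, and 9 had a MYC peak in 786-O. At 3 of them, those on chromosome 1 at 46598193 and 184020634 and on chromosome 4, parental 786-O cells also had a GFP peak, with ranks of 3255, 999 and 1111 among the 3361 parental peaks; the tagged 786-O peaks there had ranks of 13, 18 and 20 of 20034.

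Parental peaks overlapped 535 of the 7718 tagged A498 peaks (6.93%, 6.38 to 7.52), against 0.103% under random placement, and 7183 peaks were tagged-only. A smaller part of the parental list was found again in tagged cells than in 786-O: 549 of 1563 parental A498 peaks (35.1%, 32.8 to 37.5). The tagged A498 list was also the shorter, with 7718 against 20034 peaks. Of the same parental A498 peaks, 811 (51.9%) overlapped the full tagged 786-O list. Tagged A498 peaks at parental sites had a median score of 13.5, against 5.46 for tagged-only peaks. The share of tagged peaks at parental sites was 4.50% under a 50% reciprocal overlap, 22.1% with both lists limited to 1563 peaks, and 3.86% without the 1 Mb bins that were dense in parental peaks, an alternative added after the data were seen.

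GFP peaks of parental cells, which carry no tag, were partly common to both lines. Of the parental A498 peaks, 733 (46.9%, 44.4 to 49.4) overlapped a parental 786-O peak, and 727 of the parental 786-O peaks (21.6%) overlapped a parental A498 peak. Across these 727 sites, the scores in both parental lists were correlated (Spearman's rho 0.72). The highest parental 786-O peak, on chromosome 17 at 19091278 to 19091579, was the fourth highest in parental A498 and was called in both tagged libraries, with rank 32 in 786-O and rank 3 in A498. The highest parental A498 peak, on chromosome 1 at 16839158 to 16840862, had rank 6 in parental 786-O. The other parental A498 peaks named were on chromosome 17 at 56708726, 56736196 and 19091271 and on chromosome 11 at 62607568. The other parental 786-O peaks named were on chromosome 17 at 19015201, chromosome 13 at 113951161, chromosome 1 at 28975010 and chromosome 10 at 51827421.

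Parental peaks were also crowded into few places. In all, 41 bins of 1 Mb held 10 or more parental peaks in at least 1 of the lines, and 14 did so in both. These bins were chosen after the values were seen. They held 44.7% of the parental A498 peaks and 17.3% of the parental 786-O peaks, against 6.58% of all tagged A498, 5.06% of all tagged 786-O and 3.27% of MYC peaks. Tagged-only peaks, from which peaks at parental sites had been removed, lay there in 3.29% of cases in 786-O and 3.49% in A498. The fullest was on chromosome 4 from 49 to 50 Mb, with 92 parental A498, 48 parental 786-O and 1 MYC peak. Others were on chromosome 10 from 42 to 43 Mb, with 67 parental A498, 51 parental 786-O and 4 MYC peaks, and on chromosome 16 from 46 to 47 Mb, with 50, 38 and 3. Some bins dense only in parental 786-O were rich in MYC peaks. Chromosome 19 from 1 to 2 Mb held 2 parental A498, 13 parental 786-O and 73 MYC peaks. The mitochondrial genome had 19 peaks in parental A498, 2 in parental 786-O, 3 in each tagged list and none listed for MYC.

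The 10 highest tagged-only sites of 786-O were all called in A498. By the sum of ranks, the leading shared sites were chromosome 11 at 8008444, with rank 1 in both lines, chromosome 19 at 49621787, with ranks 3 and 7, and chromosome 5 at 25544631, with ranks 2 and 12. Chromosome 12 at 4429864, chromosome 16 at 68297870, chromosome 11 at 34378905, chromosome 1 at 222817163, chromosome 9 at 110103253 and chromosome 16 at 89159947 and 4233133 completed the 10, of which 7 had a MYC peak. In all, 2970 of the 7183 tagged-only A498 peaks (41.3%, 40.2 to 42.5) overlapped a tagged-only 786-O peak, against 0.545% under random placement and 1.53% when peaks were moved within 50 kb. In the other direction, 2827 of the 17596 tagged-only 786-O peaks (16.1%, 15.5 to 16.6) were shared with A498.

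Sharing went with peak strength. Shared 786-O peaks had a median score of 35.4 and a median width of 802 bp, against 10.1 and 316 bp for those not shared, a score difference of 25.3 (24.1 to 26.3). In A498 the medians were 6.74 and 4.81, a difference of 1.93 (1.81 to 2.21), which was 3.29 (2.84 to 3.67) under a 50% reciprocal overlap. Of the lowest 10% of tagged-only 786-O peaks by score 1.42% were shared with A498, and of the highest 10% the share was 64.4% (62.1 to 66.6). Scores at the 2827 shared 786-O peaks were correlated with those of the overlapping A498 peaks (Spearman's rho 0.49 across peaks). Of the highest 10% of tagged-only 786-O peaks 35.1% had no peak in the full tagged A498 list. The peak on chromosome 7 at 25899886 to 25900619 (score 237, rank 14) and that on chromosome 3 at 52436197 to 52438016 (score 232, rank 19) had no tagged A498 peak, although the latter had a parental A498 peak with a score of 4.04. Others in 786-O were on chromosome 7 at 2547622, chromosome 13 at 76123278 and chromosome 9 at 133837953.

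All of the 5 highest tagged-only A498 peaks without a tagged-only 786-O partner did have a peak in the full tagged 786-O list; they were on chromosome 1 at 46598193 and 184020634, chromosome 4 at 106629544, chromosome 16 at 3070097 and chromosome 21 at 34915569. Among all 4213 such A498 peaks, 938 (22.3%) overlapped a tagged 786-O peak that itself lay at a parental 786-O peak. The share of A498 peaks found in 786-O was 56.6% without any parental subtraction and 12.7% under a 50% reciprocal overlap. The share of tagged-only 786-O peaks found in A498 was 33.9% with both lists limited to 7183 peaks and 5.20% under the reciprocal rule.

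**Figure D2:**
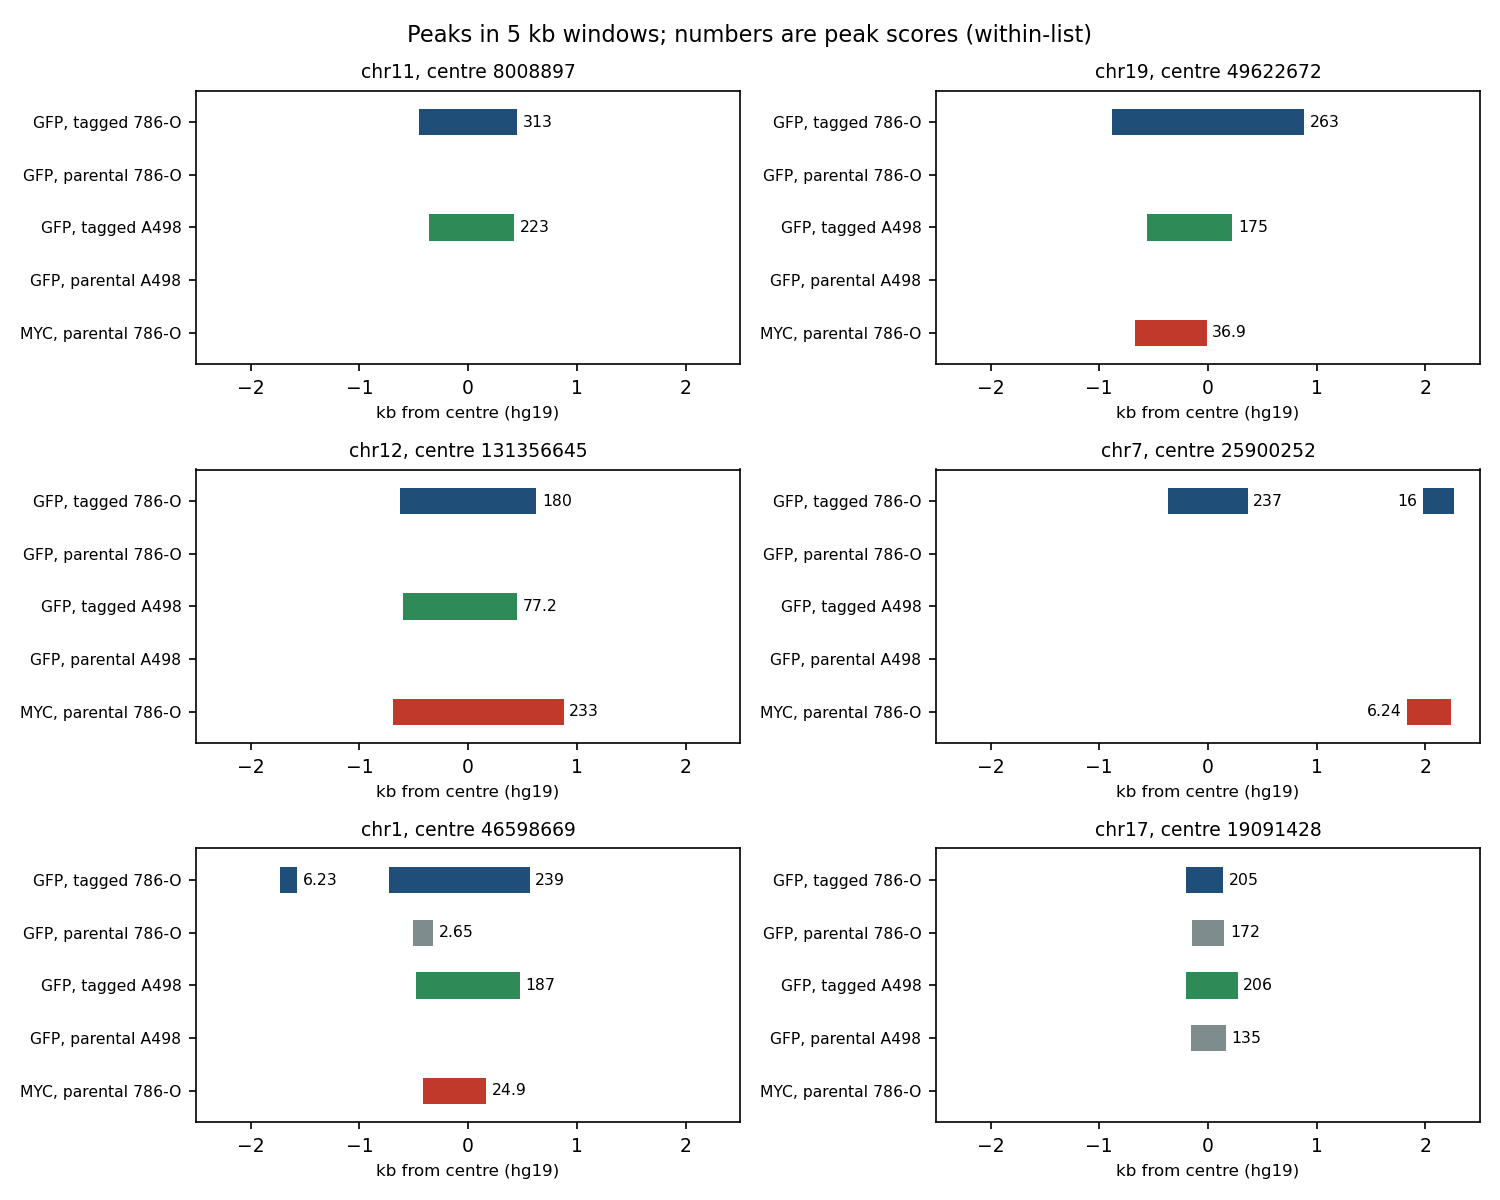
Peaks of the 5 lists in 5 kb windows around named sites (hg19, x axis in kb from the centre); each bar is a peak and the number beside it is the authors' score, comparable only within its list. The site on chromosome 11 was called in both tagged lists alone (scores 313 and 223), the site on chromosome 12 also for MYC (score 233), and the site on chromosome 17 in every GFP list.

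The chromosomes of the A498 peaks differed between those shared with 786-O and those not. Of the peaks on chromosomes 1 to 22 and X, chromosome 2 held 13.1% (12.1 to 14.1) of the unshared A498 peaks and 7.42% (6.50 to 8.42) of the shared ones. Chromosome 7 held 12.3% against 7.66%, and chromosome 8 held 8.26% against 4.32%. Chromosomes 21 (2.25% against 1.08%) and X (3.07% against 1.59%) also held a larger share of the unshared peaks. Chromosome 14 held 0.431% (0.256 to 0.681) of the unshared and 1.72% (1.28 to 2.26) of the shared peaks, and chromosome 18 held 0.120% against 0.675%. Of tagged-only 786-O peaks, chromosomes 2, 7 and 8 held 7.14%, 5.97% and 4.04%; the first and last lay within the intervals of the shared A498 peaks, and that of chromosome 7 lay below its interval (6.72 to 8.67).

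**Figure D3:**
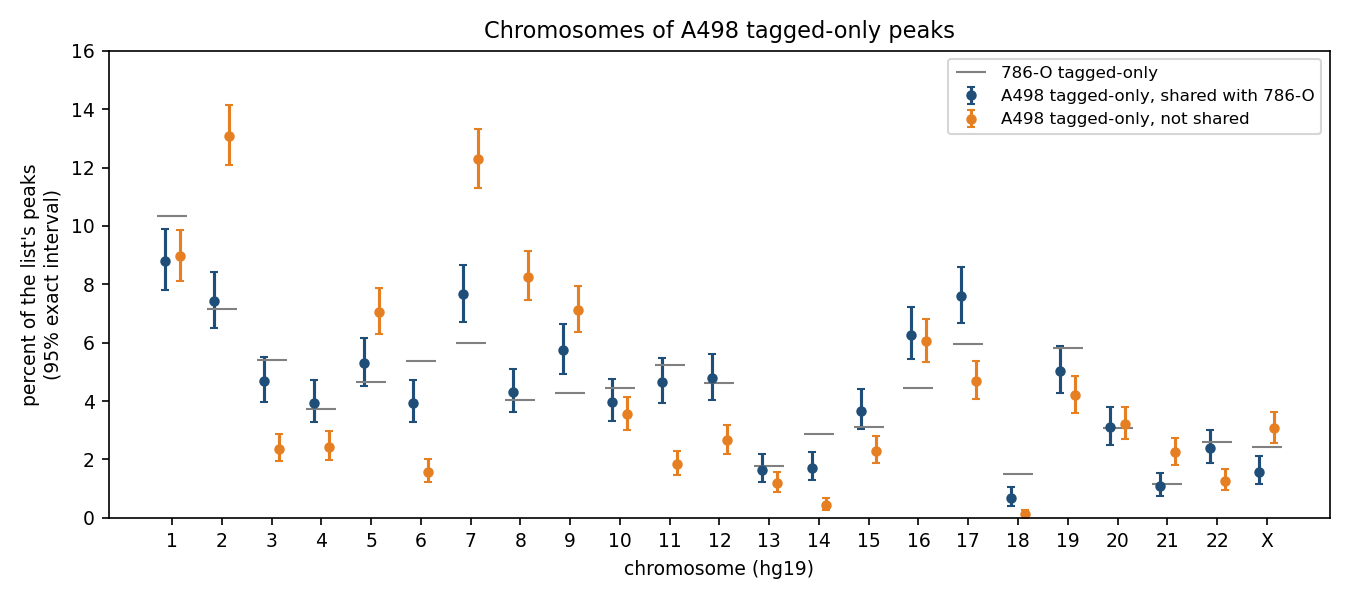
Percent of A498 tagged-only peaks on each chromosome, for peaks shared with 786-O (blue) and not shared (orange), with 95% exact intervals; grey lines give the percent of 786-O tagged-only peaks. With intervals that do not overlap, unshared peaks lie above shared ones on chromosomes 2 (13.1% against 7.42%), 5, 7, 8, 21 and X, and below on chromosomes 3, 4, 6, 11, 12, 14, 15, 17, 18 and 22.

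MYC, a transcription factor of growth and ribosome biogenesis genes, had peaks at many of the tagged-only sites of 786-O, while 3 of the 10 highest tagged-only sites had no MYC peak. The MYC library is so named by its title and antibody, but its target field names P300, a coactivator, and every share with MYC given here rests on the title. The tagged-only and MYC peaks of best rank sum were on chromosome 12 at 131356017 to 131357273 (ZNF395-eGFP rank 50, MYC rank 106), chromosome 19 at 1862337 to 1864638 (ranks 140 and 19), chromosome 1 at 41445196 to 41446213 (ranks 71 and 108), chromosome 7 at 150759448 to 150760691 (ranks 117 and 141) and chromosome 17 at 17494583 to 17495503 (ranks 88 and 185). The tagged-only peaks on chromosome 11 at 8008444, chromosome 5 at 25544631, chromosome 2 at 39455162, chromosome 7 at 25899886 and chromosome 9 at 110103253 had no MYC peak, although they held ranks 1, 2, 4, 14 and 17 in tagged 786-O. Conversely, the MYC peak on chromosome 5 at 131794550 to 131795718 (MYC score 254.7, rank 74) had no tagged 786-O peak. The same held for MYC peaks on chromosome 2 at 202122639 and 100630198, on chromosome 10 at 25305184 and on chromosome 1 at 110162101, with MYC ranks of 79, 92, 113 and 142.

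Of the tagged-only 786-O peaks, 10355 (58.8%, 58.1 to 59.6) overlapped a MYC peak, against a mean of 0.820% under random placement and 2.89% when peaks were moved within 50 kb. Of the MYC peaks, 10461 (51.8%, 51.1 to 52.5) overlapped a tagged-only peak. The share with MYC was 31.9% in the lowest 10% and 86.2% (84.5 to 87.8) in the highest 10% of tagged-only scores. Scores at common sites were weakly correlated across 10355 peaks (Spearman's rho 0.17). The 786-O peaks shared with A498 overlapped MYC in 87.6% (86.3 to 88.8) of cases and those not shared in 53.3% (52.5 to 54.1). Sites in tagged-only 786-O, tagged-only A498 and MYC together numbered 2477, and 6891 of the tagged-only 786-O peaks (39.2%) were in neither of the other lists. At the 2477 common sites the midpoint of the 786-O peak lay a median of 106.5 bp from the nearest MYC midpoint and 101 bp from the nearest A498 midpoint. These sites were chosen because the peaks overlap, and the 786-O peaks there had a median width of 847 bp. Short distances follow in part from that choice, and no expected distance was computed.

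Of the tagged-only A498 peaks, 48.0% (46.8 to 49.2) overlapped a 786-O MYC peak. Those shared with 786-O did so in 85.3% of cases and those not shared in 21.7% (20.5 to 22.97), again without matching for score or width. The parental lists serve as the background of the GFP antibody. Parental 786-O peaks overlapped MYC peaks in 60.5% (58.8 to 62.1) of cases, a share whose interval overlaps that of all tagged 786-O peaks (60.6%, 59.97 to 61.3), and parental A498 peaks did so in 15.9% (14.1 to 17.8). Outside the bins dense in parental peaks these shares were 68.0% (66.2 to 69.7) in parental 786-O and 26.6% (23.7 to 29.7) in parental A498, and inside them 24.3% and 2.58%. Tagged 786-O peaks at parental sites overlapped MYC in 73.6% (71.8 to 75.4) of cases. The share with MYC rose with score, and the 3361 highest tagged-only peaks, as many as the parental list holds, overlapped MYC in 85.0% (83.8 to 86.2) of cases. The parental 786-O and MYC lists were called against the same control library. Under a 50% reciprocal overlap 37.9% of tagged-only 786-O peaks were shared with MYC and 33.1% of MYC peaks with the tagged-only list.

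**Figure D4:**
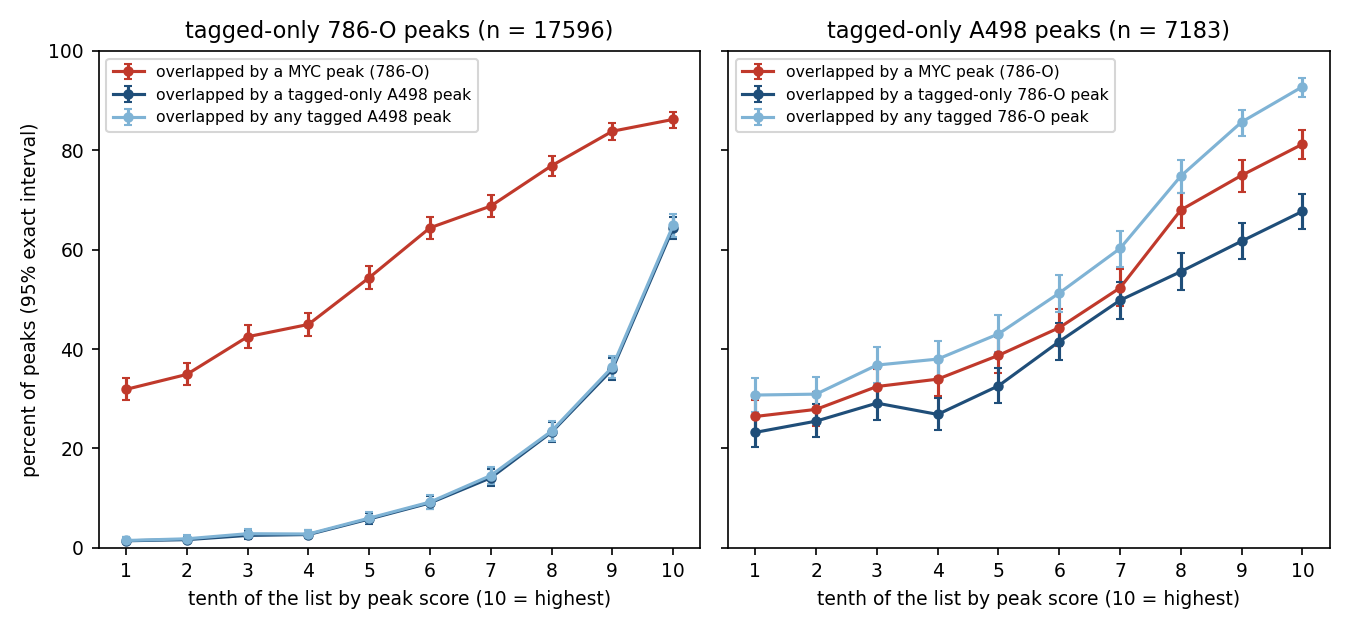
Percent of tagged-only peaks (left 786-O, right A498) overlapped by a MYC peak (red), by a tagged-only peak of the other line (dark blue) or by any tagged peak of the other line (light blue), for each of 10 equal parts of the list by score, with 95% exact intervals. In 786-O the MYC share goes from 31.9% in the lowest part to 86.2% in the highest, and the share found in A498 from 1.42% to 64.4%.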

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

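Both score differences kept their direction under the 2 alternatives run on each, and a share of peaks has no direction to reverse. Of the 58 values whose reported one has a 95% interval, 18 stayed within it and 40 left it; the other 2 are expectations from placement within 50 kb, which have none. The share of tagged peaks at parental sites (12.2% in 786-O, 6.93% in A498) was 3.80% and 4.50% with 50% reciprocal overlap, 9.13% and 5.92% with midpoints within 200 bp, 11.4% and 7.88% in the upper 50% of scores, 26.8% and 22.1% with lists limited to equal length, 11.6% and 6.31% without the widest 1% of peaks, and 10.5% and 3.86% without the dense parental bins. The share of tagged-only A498 peaks found in tagged-only 786-O (41.3%) was 12.7% with reciprocal overlap, 30.5% with midpoints, 58.4% in the upper 50% of scores, 36.0% with equal lists, 39.96% without the widest peaks, 56.6% without parental subtraction and 46.1% with the peaks of either parental list removed from both lines. The share of tagged-only 786-O peaks at MYC peaks (58.8%) was 37.9%, 44.7%, 52.8%, 53.8% and 57.7% under the first 5 of these and 60.6% without subtraction. The reciprocal rule lowers shares by construction where a narrow peak lies in a wide one. Keeping the upper 50% of scores shortened both lists, so the 52.8% counts only MYC peaks in the upper 50% of their own list. It therefore does not contradict the rise of the MYC share with score, which was taken against the full MYC list. The cause of the other moves was not tested. The score difference between shared and unshared peaks was 23.2 in 786-O and 3.29 in A498 with reciprocal overlap, and 2.76 in A498 without subtraction. Removing unplaced contigs and the mitochondrial genome moved none of the shares out of its interval. Dense bins and placement within 50 kb were chosen after seeing the data. Alternatives that need an annotation (promoter windows, promoter-matched placement, gene lists, motifs, promoter peaks apart) were not run. No paired analysis was run: each group is 1 library, and tagged and parental libraries form only 1 pair per line. Peak lists hold no read counts, so whether the shorter A498 lists reflect depth or binding is not resolved by depth here.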

Other observations

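The tests of carry-over from tagged cells, of copy number, of subtraction over all A498 peaks and of midpoints were chosen after the result was seen, as were the chromosomes and blocks named; the other tests were written down before their results were seen.

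The proportion of 786-O MYC sites with a tagged peak differed among chromosomes in both lines. The full tagged lists were used here, so sites with a parental peak are included. Chromosome 7 had a tagged A498 peak at 25.2% (95% interval 22.5 to 28.0) of its MYC sites and chromosome 18 at 6.15% (3.74 to 9.44). Tagged 786-O peaks were found at 66.4% (63.4 to 69.3) and 55.02% (49.3 to 60.7) of the same sites. Blocks of 20 Mb were kept only if they held at least 20 MYC sites. Among these the lowest tagged A498 shares were 1.08% (0.0272 to 5.85) of 93 MYC sites on chromosome X and 1.25% (0.0316 to 6.77) of 80 on chromosome 18, both from 40 to 60 Mb. The highest were 33.3% (25.7 to 41.7) of 144 sites on chromosome 8 from 140 to 160 Mb and 37.0% (19.4 to 57.6) of 27 sites, few enough for a wide interval, on chromosome 4 from 180 to 200 Mb. At those 4 blocks the tagged 786-O share was 65.6%, 50.0%, 59.0% and 66.7%. Over 155 blocks the SD was 6.25 percentage points around a mean of 17.3% in A498 and 7.36 around 61.1% in 786-O, which was 1.55 and 1.41 times that of counting alone.

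A498 peaks not shared with 786-O were over-represented on chromosomes 2, 7 and 8, which together held 33.6% of the unshared and 19.4% of the shared peaks, a ratio of 1.73 (1.59 to 1.90). A few dense clusters are argued against, because the 5 fullest 1 Mb bins held at most 17.4% of the unshared peaks of any of these chromosomes. Repeat background of the kind seen in parental cells is argued against as well, since the ratio was 1.71 (1.47 to 2.01) without every 1 Mb bin that held a parental peak. That removal left 1243 unshared and 766 shared peaks. It cannot address background called only in the tagged A498 library. A higher copy number in A498, which would let weak peaks pass the threshold, remains a candidate that these values cannot decide. On chromosomes 1 to 22 and X, 3238 unshared peaks had no tagged 786-O peak. Chromosomes 2, 7 and 8 held 37.9% (35.6 to 40.3) of these in the lower 50% of scores and 31.6% (26.5 to 36.96) in the top 10%. The difference was 6.35 percentage points (0.839 to 11.7), and over all unshared peaks it was 6.44 (1.74 to 11.4). Chromosomes 2, 7 and 8 were picked from these same unshared peaks, and the intervals treat peaks as independent, so neither difference is separate support. Over all tagged-only A498 peaks the shares of 30.7% and 22.5% decide nothing, since the mix of shared and unshared peaks alone gives 29.7% and 23.9%; copy number was not measured in these lists, and binding that differs between the lines stays open and was not tested.

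Under the 1 bp rule that defines a partner, most strong A498 sites that lack a tagged-only 786-O partner lack it through the subtraction of parental peaks. Of the 232 such peaks in the top 10% of A498 tagged-only scores, 77.6% (71.7 to 82.8) overlapped the full tagged 786-O list. A tagged 786-O peak that is not tagged-only is one removed for overlap with a parental 786-O peak. By the stricter rule, 56.0% (49.4 to 62.5) had a midpoint within 200 bp of a midpoint in the full tagged 786-O list. Over all 4213 unpartnered peaks the shares were 22.3% (21.0 to 23.6) and 14.2% (13.2 to 15.3), so subtraction is argued against as the explanation for most of them. Whether unpartnered peaks are mainly weak peaks near the calling threshold stays open: of the top 10% of A498 tagged-only peaks, 7.24% (5.46 to 9.39) had no overlapping peak in the full tagged 786-O list but 28.3% (25.004 to 31.7) had none by midpoint, against 69.3% and 78.03% of the lowest 10%. Whether the remaining strong sites are specific to A498 was not tested.

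GFP peaks in parental 786-O, which carry no tag, overlapped MYC in 60.5% of cases, against 60.6% of the tagged list, 58.8% of tagged-only peaks and 68.0% of the parental peaks outside the bins dense in them, but 85.0% (83.8 to 86.2) of the 3361 highest tagged-only peaks, a list of equal length picked by score, with which the MYC share rises. High-scoring tagged-only peaks were also wider than parental ones. By midpoints within 200 bp, MYC shares were 64.0% and 66.0% in parts 9 and 10 of tagged-only scores. No midpoint share was computed for the parental peaks, so these values cannot be set beside the 60.5% by 1 bp overlap. How much of the excess reflects width is open. An artefact of the input library that the MYC and parental lists share stays open. MYC overlapped 20.0% (17.3 to 22.9) of the 800 parental peaks absent from the tagged list, which has another input. It overlapped 73.1% (71.3 to 74.8) of the 2561 present in it. This split cannot decide the question, because the tagged list itself overlapped MYC in 60.6% of cases. Peaks present in it are thus more often at MYC sites whatever the input does. Random placement of all parental 786-O peaks gave a mean of 0.620% at MYC peaks. Carry-over of tagged material is argued against only as the sole source of the parental peaks, because 24.0% (18.3 to 30.5) of the 200 strongest tagged 786-O peaks had a parental peak. Some carry-over stays open, since that share was 12.2% over all tagged peaks and tagged peaks at parental sites had the higher median score (27.0 against 11.8). However, tagged and parental 786-O scores were only weakly correlated across the 2438 tagged peaks at parental sites (Spearman's rho 0.13). Background of the antibody at strongly MYC-bound sites also stays open: MYC peaks with a parental peak had a median score percentile of 74.2 (72.4 to 75.9) in the MYC list, but parental and MYC scores had a Spearman's rho of 0.01 across the 2032 parental peaks at MYC sites, and accessibility was not measured in these lists.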
